A study of Homo sapiens with 30 samples.

How the data were processed

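RNA was measured by sequencing in 30 libraries of the prostate cancer cell lines VCaP, LNCaP and LAPC4, in 15 groups of 2 libraries. Per the labels' protocols, polyadenylated RNA from cells grown in plates was made into libraries with a TruSeq kit and sequenced as read pairs on an Illumina HiSeq instrument. Cells received DMSO or AU-15330 at 0.1 or 1 µM, and groups, doses and times were taken from the labels. All libraries in the labels were used.

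For the longer VCaP, the LNCaP and the LAPC4 experiments the authors deposited whole-number read counts per gene symbol, 1 file per library. For the short VCaP experiment the authors deposited expected counts, fractional estimates of reads per Ensembl gene ID, and these were rounded to whole numbers before testing. Both units were read from the values, since the file headers name only an identifier column and a library code. The submitters' processing notes name bcl2fastq, STAR and HTSeq and the builds GRCh38 and hg38. Their versions, the role of each, the annotation release and the strand counted were not given in the sources used here, nor was the program behind the fractional values. Each file was unnormalised, with library totals that differed, and held no summary lines.

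The files by symbol held 19907 genes (VCaP) or 19940 (LNCaP and LAPC4), of which 18802 were current GENCODE v44 symbols and 19291 current or older ones. In the LNCaP and LAPC4 files 33 symbols appeared 2 times, and their 66 entries were left out, 0.292 to 0.306% of counts in LNCaP and 0.276 to 0.301% in LAPC4. Of 33110 gene IDs in the short experiment 33034 were paired with a GENCODE v44 symbol without their version, 22333 with the same version, and 13 that shared a symbol were kept under their ID. Coordinates in the report come from GENCODE v44 on GRCh38, whose release may differ from the one behind the counts.

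Each experiment was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries scaled by TMM factors, and a robust quasi-likelihood model with 1 term per group was tested two-sided. The adjusted p is Benjamini-Hochberg over all genes tested in a comparison, and genes with an adjusted p under 0.05 are called changed. Standard errors are the log2 change divided by the square root of the F statistic. CPM are counts scaled to a common library total with the TMM factors, and are given as group means, with the SD of the 2 libraries after ± where printed. Tests covered 16311 genes in the short VCaP experiment, 15747 in the longer one, 15132 in LNCaP and 16426 in LAPC4. Each treated group was compared with the DMSO group of its experiment, 24 h with 4 h in VCaP, 24 h with 12 h in LNCaP and 1 µM with 0.1 µM in LAPC4. DMSO was sampled at 24 h, and at 2 h in the short experiment, so other times have no vehicle of their own time. The 24 h effects of 1 µM were compared between lines by interaction terms in a joint fit of 12 libraries and 16342 genes.

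Called genes shared between comparisons were counted by direction beside the number that independent lists would share. That number takes every gene as equally likely to be called, which was not checked. For comparisons with the same DMSO libraries, counts of all groups, DMSO included, were also simulated in 20 runs with no gene changed, since 2 controls cannot be split into separate pairs. Few calls can arise where no gene changes, so these runs cannot gauge how much shared controls add to an overlap of many calls. Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with the correlation estimated from the data. Unlike the preset test, that test rests on the residual degrees of freedom, libraries minus groups. These were 4 in the short VCaP experiment, 5 in the longer one, 3 in LNCaP and LAPC4 and 6 in the joint fit. Fewer of them make a list harder to call, so passing it cannot be compared between experiments. Lists with at least 5 tested members were tested. The 22 lists, with members from general knowledge of each programme, were SWI/SNF subunits, androgen-induced genes, prostate lineage transcription factors, ERG-associated genes, MYC-induced ribosome biogenesis, S-phase, G2/M-phase, cholesterol synthesis, integrated stress response, endoplasmic reticulum chaperone, p53-induced, interferon-stimulated, immediate-early, hypoxia-induced, nuclear oxidative phosphorylation, luminal epithelial, basal epithelial, mesenchymal, neuroendocrine, stromal and endothelial, and blood cell genes, and mitochondrially encoded mRNAs.

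The groups, comparisons, tests, gene lists and naming rule were chosen before the data were examined. The rule named SMARCA2, SMARCA4, PBRM1, FOXA1, ERG, MYC, KLK3, TMPRSS2 and FKBP5 in every comparison. Results of some further genes are not reported here. In each comparison of 1 µM at 24 h with DMSO it added the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 3, and every treated library on the same side of every DMSO library, passing over symbols of clones, uncharacterised loci, non-coding and antisense RNAs and ribosomal proteins. In other comparisons it added the first 3 each way, and from each list up to 3 called members with the smallest p. Some genes in interactions with 3 or fewer counts in a compared group were not printed.

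The alternatives chosen beforehand were DESeq2 1.42.0 (Wald test), RLE factors, library totals as the only scaling, no filter on low counts, a filter of at least 1 CPM in at least 2 libraries, fits of only the groups compared, a replicate block, leaving out each library in turn, a change of at least 2-fold for the overlaps, an estimated correlation and fry for the lists. Leaving mitochondrially encoded genes out of the short VCaP fits was added after seeing their share of counts rise.

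The gene tests and list tests were run once per comparison on simulated counts drawn from the means and totals of these libraries. Small sets of genes were changed by 1.25, 1.5, 2 and 4-fold, and the numbers in brackets are all genes tested. Far fewer genes were changed than were called in the real 24 h comparisons. Recovery, false calls and scaling were therefore not checked at so large a share of changed genes. In the VCaP 24 h comparison 56, 82, 89.8 and 93.9% of those genes were recovered (15533 genes), in VCaP at 2 h 42.9, 60.0, 87.5 and 94% (16133 genes), in LNCaP at 24 h 46.9, 71.4, 76 and 94% (14935 genes), in LAPC4 at 1 µM 70.8, 77.1, 92 and 93.9% (16061 genes) and in the interaction of LNCaP and LAPC4 47.9, 68, 89.1 and 88% (15828 genes). Unchanged genes made up 3.6, 3.4, 5.3, 5.8 and 6.6% of the calls, in the same order. A raised list was called in each of these 5 comparisons, and 0 of 20 unchanged lists were. Genes were drawn independently of each other, so false calls of lists whose members vary together were not checked.

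A value of 1 CPM stood for 28.9 to 36.7 reads in the short VCaP libraries, 23.7 to 26.3 in the longer ones, 23.6 to 26.1 in LNCaP and 57.6 to 74.7 in LAPC4. The coefficient of variation between replicates beyond counting error was 0.0404 in the short VCaP experiment, 0.0436 in the longer one, 0.0407 in LNCaP and 0.0327 in LAPC4. The mean chi-square per gene between replicates, 1 under counting error alone, was 2.57 to 6.17, so replicates differed by more than counting error. With 2 libraries per group neither a test of single outlying samples nor a count of other splits of the samples applies.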

Results

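The data were 30 RNA-seq libraries in 15 groups of 2, from 4 experiments on 3 human prostate cancer cell lines that respond to androgen. VCaP carries the TMPRSS2-ERG gene fusion, and LNCaP and LAPC4 were each derived from a lymph node metastasis. AU-15330 is a degrader, a molecule that brings the SWI/SNF chromatin remodelling ATPases SMARCA2 and SMARCA4, and the subunit PBRM1, to an E3 ubiquitin ligase. A short VCaP experiment held vehicle (DMSO) at 2 h and AU-15330 at 1 µM for 0.5, 1 and 2 h. A longer VCaP experiment held DMSO at 24 h and 1 µM for 4, 8, 12 and 24 h. The LNCaP experiment held DMSO at 24 h and 1 µM for 12 and 24 h, and the LAPC4 experiment held DMSO, 0.1 µM and 1 µM, all at 24 h. Total counts per library were 28.9 to 36.7 M in the short VCaP experiment, 23.7 to 26.3 M in the longer one, 23.7 to 26.2 M in LNCaP and 57.8 to 74.9 M in LAPC4. Values are log2 changes ± SE or CPM, counts scaled to a common library total, as the mean of n = 2 libraries per group, and genes are said to have risen or fallen only where the adjusted p was below 0.05. The p-values measure only the spread between these libraries, which may be technical. Largest rises and falls are ranked by the naming rule, only among called genes past its expression floor, an average log2 CPM of at least 3.

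Positions of the genes followed throughout, all protein-coding, are given on GRCh38 with GENCODE v44. The degrader's targets are SMARCA2 (chromosome 9, 1980290 to 2193624), SMARCA4 (chromosome 19, 10960932 to 11079426) and PBRM1 (chromosome 3, 52545352 to 52685917). The transcription factors are the pioneer factor FOXA1 (chromosome 14, 37589552 to 37596059), the ETS factor ERG (chromosome 21, 38380027 to 38661780) and MYC (chromosome 8, 127735434 to 127742951). The androgen-regulated genes are KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), its neighbour KLK2 (chromosome 19, 50861568 to 50880567), the serine protease TMPRSS2 (chromosome 21, 41464300 to 41531116) and the co-chaperone FKBP5 (chromosome 6, 35573585 to 35728583).

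The short VCaP experiment addresses which transcripts change first once the degrader is added. At 0.5 h the immediate-early genes, which respond to many stimuli within minutes, were higher than in DMSO. FOS rose by 2.36 ± 0.11 (from 7.3 ± 0.565 to 37.5 ± 5.76 CPM; adjusted p = 3.62e-13), FOSB by 1.76 ± 0.12 and EGR1 by 1.58 ± 0.11. MYC rose by 0.67 ± 0.05 (from 316 to 502 CPM), ERG by 0.41 ± 0.04 and TMPRSS2 by 0.35 ± 0.05. The largest falls were in the bHLH factor ATOH8 (-1.28 ± 0.08), the phosphatase DUSP2 (-1.23 ± 0.07; from 45.7 to 19.5 CPM) and the zinc finger factor GATA6 (-1.06 ± 0.09). The cyclin-dependent kinase inhibitor CDKN1A also fell (-0.86 ± 0.07). FOXA1 at 0.04 ± 0.05 was not past the test, and SMARCA2, SMARCA4, PBRM1, KLK3 and FKBP5 were not called either. Of 20 immediate-early genes tested, 12 were higher and 1 lower (13 and 2 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 3.3e-18, adjusted p = 0.013 with an estimated correlation). The lower member was KLF10, a zinc finger factor, and 5 of 15 prostate lineage transcription factors were higher (7 and 0 adjusted over the list alone; camera adjusted p = 1.22e-08, adjusted p = 0.0538 with an estimated correlation). Among 23 cholesterol synthesis genes 2 were lower, among them NSDHL (-0.32 ± 0.08), with 0 and 7 adjusted over the list alone (camera adjusted p = 8.41e-10, adjusted p = 0.21 with an estimated correlation). In all, 181 genes were higher and 142 lower of 16311 tested, 13 and 12 of them by at least 2-fold. The DMSO libraries were taken at 2 h, not at 0.5 h. The total of 323 was 112 without 0.5 h replicate 1, 106 without 0.5 h replicate 2, 99 without DMSO replicate 1 and 138 without DMSO replicate 2, and 901 when only these 4 libraries were fitted.

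At 1 h the largest rise was in the prostaglandin receptor gene PTGER4 (chromosome 5, 40679915 to 40693735), by 1.66 ± 0.11 (from 8.97 to 28.5 CPM; adjusted p = 3.41e-09). FOSB (1.31 ± 0.12), EGR1 (1.20 ± 0.12) and JUN (0.57 ± 0.06) were still higher, as was MYC (0.55 ± 0.05). TMPRSS2 (0.37 ± 0.05) and ERG (0.259 ± 0.045) were higher too. TXNIP, which encodes the thioredoxin-interacting protein, fell by 1.72 ± 0.09 on the log2 scale (from 134 to 41 CPM), followed by CDKN1A (-0.91 ± 0.07) and ATOH8 (-0.79 ± 0.07). The pseudogene MTND2P28, which can share reads with its mitochondrial parent gene, was at 1.36 ± 0.10 and is uncertain. Of 20 immediate-early genes 7 were higher and 1 lower (11 and 2 adjusted over the list alone; camera adjusted p = 1.87e-10, adjusted p = 0.0402 with an estimated correlation). The prostate lineage factors had 4 members higher and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 5.15e-09, adjusted p = 0.0487 with an estimated correlation). Mitochondrially encoded mRNAs, subunits of the respiratory chain, had 8 of 13 members higher (9 and 0 adjusted over the list alone), and the list's call was lost with an estimated correlation (camera adjusted p = 2.97e-19, adjusted p = 0.163 with an estimated correlation). The share of counts on mitochondrial genes was 5.0 and 4.95% in the DMSO libraries, 5.57 and 5.85% at 1 h and 7.02 and 7.25% at 2 h. In all 121 genes were higher and 94 lower, and with mitochondrially encoded genes left out the counts were 104 and 96. Of the calls 56.3% were higher, and 39% when libraries were scaled by their totals only. The total of 215 was 98 without 1 h replicate 2, 120 without DMSO replicate 1 and 70 without DMSO replicate 2.

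At 2 h, against time-matched DMSO, PTGER4 rose by 2.90 ± 0.10 (from 8.97 ± 2.28 to 67 ± 3.26 CPM; adjusted p = 1.39e-14), the stress-induced gene NDRG1 by 0.71 ± 0.05 (from 764 to 1247 CPM), FKBP5 by 0.51 ± 0.05 and TMPRSS2 by 0.44 ± 0.05. The transcriptional repressor genes ZNF503 (2.01 ± 0.06; from 43.2 to 174 CPM) and KLF10 (1.21 ± 0.06), and BHLHE40 (1.13 ± 0.06) and BTG2 (1.21 ± 0.07), also rose. RIMBP3 was among the largest rises as well (2.00 ± 0.30). The largest fall was in ENSG00000196656, named by its ID, from 23.9 CPM in DMSO to 0 in each 2 h library (-12.6 ± 0.33). It is uncertain, since the program behind the fractional counts was not given. DUSP2 (-1.70 ± 0.08) and CDKN1A (-1.39 ± 0.07; from 59.2 to 22.6 CPM) were again lower, and MYC was now lower too (-0.17 ± 0.05; adjusted p = 0.0191). Of 33 androgen-induced genes 14 were higher and 0 lower (15 and 2 adjusted over the list alone; median 0.09; camera adjusted p = 2.39e-12, adjusted p = 0.0771 with an estimated correlation). With library totals only, 13 were higher and 2 lower, with a median of 0.0455. ERG was higher (0.35 ± 0.04), and KLK3, at 0.03 ± 0.08, was not among the calls. The immediate-early genes now went both ways, with JUN at -0.59 ± 0.06 and ZFP36, an mRNA-destabilising factor, at 1.07 ± 0.12, and the list had 7 higher and 4 lower. S-phase genes had 5 of 25 members lower (0 and 7 adjusted over the list alone; camera adjusted p = 0.000139, adjusted p = 0.526 with an estimated correlation), led by UHRF1 (-0.46 ± 0.05) and the cyclin CCNE2 (-0.36 ± 0.05), and 8 lower with library totals only (median -0.1354, from -0.0878). Among SWI/SNF subunits BCL7A (0.47 ± 0.06), BICRA and BICRAL rose, but the list's median of 0.045 became -0.0027 with library totals only (camera adjusted p = 0.00439, adjusted p = 0.251 with an estimated correlation). Mitochondrially encoded mRNAs had 11 of 13 members higher (12 and 0 adjusted over the list alone), with a median of 0.70 and MT-CO2 at 0.86 ± 0.06 (camera adjusted p = 1.7e-32, adjusted p = 0.137 with an estimated correlation). In all 656 genes were higher and 524 lower (77 and 27 by at least 2-fold), against 649 and 508 with mitochondrially encoded genes left out. Of the calls 55.6% were higher, and 34.1% with library totals only, and the total of 1180 was 654 without DMSO replicate 1 and 637 without DMSO replicate 2.

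**Figure D1:**
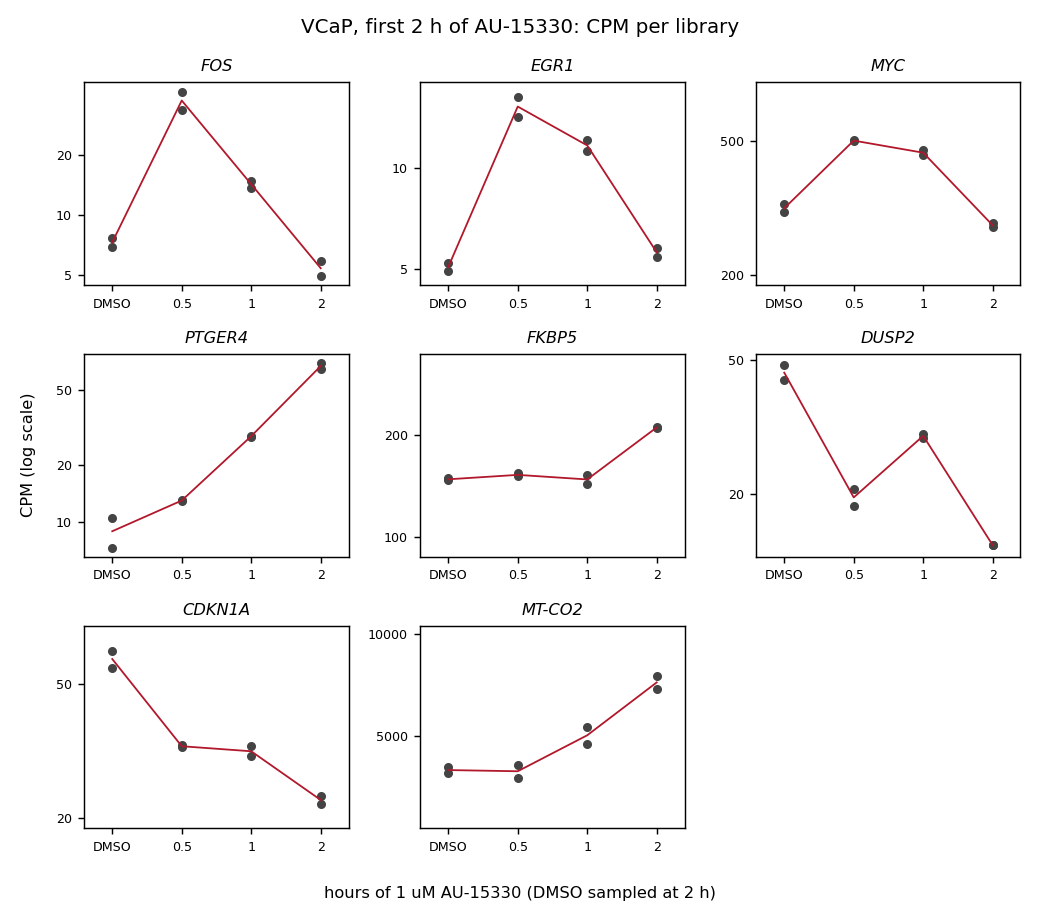
CPM on a log axis for 8 genes in the short VCaP experiment, by group (DMSO 2 h, then AU-15330 1 µM for 0.5, 1 and 2 h), with a point per library and a red line through the group means. FOS is highest at 0.5 h (37.5 CPM), PTGER4 climbs from 8.97 to 67 CPM and DUSP2 reaches 14.1 CPM at 2 h.

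The longer VCaP experiment addresses how the response develops over a day. By 4 h MYC fell by 1.23 ± 0.05 on the log2 scale (from 341 ± 8.42 to 145 ± 3.76 CPM; adjusted p = 2.77e-24), with FOXA1 at -0.81 ± 0.04 and ERG at -0.72 ± 0.04. Among androgen-induced genes KLK2 (-1.63 ± 0.04), KLK3 (-1.21 ± 0.15) and TMPRSS2 (-1.26 ± 0.05) fell, while FKBP5 rose by 2.28 ± 0.04 (from 172 to 835 CPM) and NDRG1 by 1.52 ± 0.03. The largest rises were in SHISA2 (5.08 ± 0.14), the microtubule-associated protein gene MAP1A (4.50 ± 0.19) and TCAF2 (4.11 ± 0.11), and the largest falls in the phosphate cotransporter gene SLC17A4 (-3.35 ± 0.12), LGI1 (-2.57 ± 0.10) and SPRED2 (-2.52 ± 0.10). SMARCA2 mRNA rose by 0.39 ± 0.04 and PBRM1 by 0.15 ± 0.04, while SMARCA4 was at 0.03 ± 0.05 and not called. These mRNA levels do not measure the proteins. Prostate lineage factors had 10 of 15 members lower and 3 higher (3 and 10 adjusted over the list alone; camera adjusted p = 0.000166, adjusted p = 0.0417 with an estimated correlation), and S-phase genes 18 of 25 lower and 1 higher (2 and 19 adjusted over the list alone; camera adjusted p = 8.39e-06, adjusted p = 0.0417 with an estimated correlation). ERG-associated genes had 11 of 16 members lower and 1 higher (1 and 12 adjusted over the list alone; camera adjusted p = 2.59e-07, adjusted p = 0.0417 with an estimated correlation). Endoplasmic reticulum chaperone genes had 15 of 18 lower (1 and 16 adjusted over the list alone; camera adjusted p = 4.74e-09, adjusted p = 0.0417 with an estimated correlation), led by HSPA5 at -0.95 ± 0.04. Ribosome biogenesis genes had 34 of 49 lower and 2 higher (2 and 35 adjusted over the list alone; camera adjusted p = 2.17e-06, adjusted p = 0.0417 with an estimated correlation). SWI/SNF subunits had 16 of 28 higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 0.00263, adjusted p = 0.0417 with an estimated correlation). In all 3786 genes were higher and 3752 lower of 15747 tested, 675 and 567 by at least 2-fold. The DMSO libraries of this experiment were taken at 24 h, so the 4, 8 and 12 h comparisons differ from them in time as well as in treatment.

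At 8 and 12 h several of these changes were larger in mean. KLK2 was at -3.50 ± 0.04 at 8 h and -4.54 ± 0.04 at 12 h, and KLK3 at -2.20 ± 0.16 and -2.77 ± 0.17. ERG was at -1.14 ± 0.04 and -0.90 ± 0.04. FKBP5 was higher than in DMSO, by 2.24 ± 0.04 and 1.54 ± 0.04. The cell adhesion gene MCAM fell by 4.36 ± 0.17 on the log2 scale at 8 h, and the Groucho corepressor gene TLE4 rose by 4.93 ± 0.12 at 12 h. The immediate-early gene FOS was higher by 1.29 ± 0.11 at 8 h and 2.57 ± 0.10 at 12 h. Ribosome biogenesis genes had 40 of 49 members lower at 8 h (2 and 40 adjusted over the list alone; camera adjusted p = 1.32e-09, adjusted p = 0.0283 with an estimated correlation) and 46 at 12 h (0 and 46 adjusted over the list alone; camera adjusted p = 2.96e-18, adjusted p = 0.0155 with an estimated correlation). ERG-associated genes had 12 and 13 of 16 lower, adjusted over the list alone 12 and 13 (camera adjusted p = 1.08e-08 and 1.22e-07, adjusted p = 0.0283 and 0.0448 with an estimated correlation). At 8 h 4420 genes were higher and 4307 lower, and at 12 h 4702 and 4481.

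At 24 h in VCaP, with time-matched DMSO, KLK2 fell by 6.19 ± 0.05 on the log2 scale (from 3756 ± 6.52 to 51.6 ± 0.348 CPM; adjusted p = 8.56e-50), ACPP, which encodes prostatic acid phosphatase, by 4.95 ± 0.05 (from 4150.0 to 134 CPM) and SLC17A4 by 7.86 ± 0.20. The other large falls were in the surfactant protein gene SFTPA2 (-6.02 ± 0.18), the acyl-CoA synthetase gene ACSL5 (-4.75 ± 0.10) and ARHGDIB (-4.57 ± 0.14). The largest rises were in BRINP2 (6.45 ± 0.24), TLE4 (5.38 ± 0.12; from 2.34 to 97.4 CPM), the synaptotagmin gene SYT2 (5.17 ± 0.09; from 4.74 to 171 CPM), SHISA2 (4.94 ± 0.14), the bZIP factor gene MAF (4.89 ± 0.09; from 4.83 to 143 CPM) and MAP1A (4.82 ± 0.19). FOXA1 was at -0.83 ± 0.04, ERG at -0.56 ± 0.04, MYC at -1.40 ± 0.05 (from 341 to 129 CPM), and the ETS factor SPDEF at -2.04 ± 0.06. KLK3, low in this line (17.8 CPM in DMSO), was at -2.96 ± 0.18, TMPRSS2 at -0.35 ± 0.05 and FKBP5 at 0.60 ± 0.04. SMARCA2 rose (0.40 ± 0.04), SMARCA4 fell (-0.23 ± 0.05) and PBRM1 was at 0.01 ± 0.04, not called. In all 5292 genes were higher and 5054 lower, 65.7% of 15747 tested, with 1506 and 1220 changed by at least 2-fold.

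At 24 h in VCaP 5 lists passed camera with the preset and with an estimated correlation. All 25 S-phase genes were lower (0 and 25 adjusted over the list alone; median -1.41; camera adjusted p = 3.55e-16, adjusted p = 0.0133 with an estimated correlation), among them the helicase subunit MCM4 (-1.55 ± 0.04) and the replication clamp PCNA (-1.52 ± 0.05). Of 49 ribosome biogenesis genes 47 were lower (0 and 47 adjusted over the list alone; median -0.97; camera adjusted p = 7.48e-18, adjusted p = 0.0133 with an estimated correlation), including the ornithine decarboxylase gene ODC1 (-1.56 ± 0.05) and nucleolin, NCL (-1.21 ± 0.04). Endoplasmic reticulum chaperone genes had 17 of 18 lower (0 and 17 adjusted over the list alone; median -1.07; camera adjusted p = 7.97e-10, adjusted p = 0.0419 with an estimated correlation), with HSPA5 at -1.68 ± 0.04. ERG-associated genes had 14 of 16 lower and 1 higher (1 and 14 adjusted over the list alone; median -1.19; camera adjusted p = 3.23e-08, adjusted p = 0.0277 with an estimated correlation), with the phospholipase PLA1A at -3.63 ± 0.06 and the potassium channel KCNH8 at -2.03 ± 0.06. Cholesterol synthesis genes had 16 of 23 lower and 5 higher (5 and 17 adjusted over the list alone; camera adjusted p = 0.000567, adjusted p = 0.0419 with an estimated correlation), led by HMGCS1 (-1.41 ± 0.04).

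Other lists passed camera in VCaP at 24 h only with the preset correlation. The lineage factors had 10 of 15 members lower and 4 higher (4 and 10 adjusted over the list alone; camera adjusted p = 0.00876, adjusted p = 0.0925 with an estimated correlation). The higher members were ELF3 (1.08 ± 0.07), KLF5, GRHL2 and HOXB13, named after their values were seen. G2/M-phase genes had 20 of 25 lower, among them the proliferation marker MKI67 (-0.51 ± 0.04), and 1 higher (1 and 20 adjusted over the list alone; camera adjusted p = 0.00102, adjusted p = 0.322 with an estimated correlation). Integrated stress response genes had 13 of 22 lower, such as TRIB3 (-2.20 ± 0.10) and STC2 (-2.44 ± 0.12), and 4 higher (4 and 13 adjusted over the list alone; camera adjusted p = 0.00912, adjusted p = 0.0826 with an estimated correlation). Immediate-early genes had 13 of 20 higher and 4 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.0153, adjusted p = 0.107 with an estimated correlation), with FOS at 3.11 ± 0.10. Nuclear oxidative phosphorylation genes had 19 of 29 lower and 4 higher (4 and 19 adjusted over the list alone; camera adjusted p = 0.0188, adjusted p = 0.196 with an estimated correlation).

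The remaining lists passed no test at 24 h in VCaP, and their members went both ways. Androgen-induced genes had 12 of 33 higher, including MAF and NDRG1 (1.95 ± 0.03; from 1685 to 6529 CPM), and 18 lower (12 and 18 adjusted over the list alone; camera adjusted p = 0.12). SWI/SNF subunits had 14 of 28 higher, such as SS18 (0.89 ± 0.05), BICRAL (0.87 ± 0.05) and BCL7A (1.05 ± 0.07), and 8 lower (14 and 8 adjusted over the list alone; camera adjusted p = 0.124). Genes induced by p53 had 6 of 19 higher and 8 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.241), with CDKN1A, the canonical target, at -2.70 ± 0.15. Hypoxia-induced genes had 4 of 18 higher and 12 lower (4 and 13 adjusted over the list alone; camera adjusted p = 0.119). Interferon-stimulated genes had 7 of 20 higher and 9 lower (7 and 9 adjusted over the list alone; camera adjusted p = 0.935). Luminal epithelial genes had 7 of 13 higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.422), and neuroendocrine markers 6 of 13 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.507), with the granin CHGB at 1.85 ± 0.06. Basal markers had 2 of 6 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.546), and stromal and endothelial markers 1 of 6 higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.546). Mesenchymal genes had 1 of 5 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.25, a mean of 0.02 and a downward test (camera adjusted p = 0.935). Mitochondrially encoded mRNAs had 4 of 13 higher and 2 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.935). Of 3 blood cell markers tested 0 were called, too few for a list test.

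**Figure D2:**
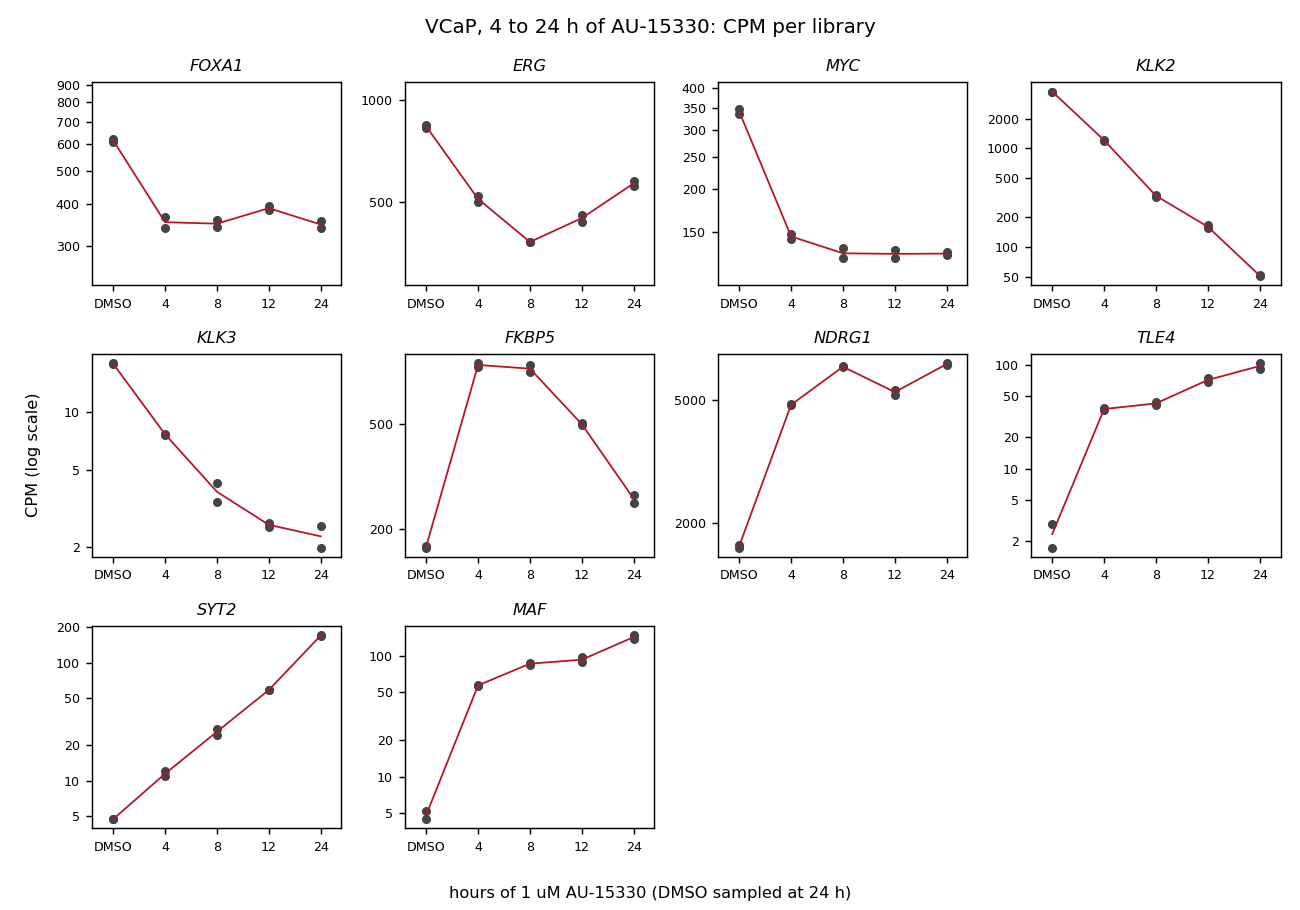
CPM on a log axis for 10 genes in the longer VCaP experiment, by group (DMSO 24 h, then AU-15330 1 µM for 4, 8, 12 and 24 h), with a point per library and a red line through the group means. KLK2 declines to 51.6 CPM at 24 h, FKBP5 peaks at 4 h (835 CPM) and MAF reaches 143 CPM.

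Testing the 24 h against the 4 h libraries directly addresses which transcripts differed between these times. There was no 4 h vehicle, so length of treatment and time in culture cannot be told apart here. The largest falls between them included KLK2, which changed by -4.55 ± 0.04 from 4 to 24 h, SFTPA2 by -5.08 ± 0.20 and SLC17A4 by -4.51 ± 0.27. The p53-regulated gene KLLN (4.23 ± 0.15), SYT2 (3.89 ± 0.08) and the myelin-associated gene NCMAP (3.10 ± 0.15) were the largest rises. FKBP5 was lower at 24 h (-1.68 ± 0.04) and TMPRSS2 higher (0.91 ± 0.05), so both lay nearer to DMSO at 24 h than at 4 h. All 25 S-phase genes were lower at 24 h (0 and 25 adjusted over the list alone; camera adjusted p = 1.39e-17, adjusted p = 0.0107 with an estimated correlation), with MCM4 at -1.28 ± 0.04. Of 49 ribosome biogenesis genes 47 were lower (0 and 47 adjusted over the list alone; camera adjusted p = 6.02e-18, adjusted p = 0.0107 with an estimated correlation). In all 4467 genes were higher at 24 h and 4491 lower. Against DMSO, 2752 genes were higher at both 4 and 24 h, 2699 lower at both and 624 called in opposite directions, where independent lists would share 1272 and 1204. Unchanged groups with the same simulated DMSO libraries shared a mean of 0.2 calls, and their log2 changes had a mean correlation of 0.495. So few calls cannot gauge the excess, part of which may come from the shared controls. The 2 VCaP experiments had separate DMSO libraries, and 435 genes were higher in both at 2 h and 4 h, 301 lower in both and 101 called in opposite directions, where independent lists would share 158 and 122.

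The LNCaP experiment addresses whether the same lineage genes change in a line without the ERG fusion. At 12 h TMPRSS2 was at -3.29 ± 0.04 (from 632 to 64.5 CPM; adjusted p = 1.24e-41), KLK3 at -2.84 ± 0.04 (from 2154 to 302 CPM), SPDEF at -2.75 ± 0.07 and MYC at -1.32 ± 0.05. FOXA1 rose by 0.18 ± 0.04 and FKBP5 by 0.11 ± 0.04. The metallothionein gene MT1X (3.19 ± 0.09), DISP2 (2.69 ± 0.16) and the interferon-induced ligase gene HERC5 (2.50 ± 0.10) were the largest rises. The largest falls were in FRMPD2 (-5.73 ± 0.20), KLK2 (-3.82 ± 0.06) and the tetraspanin-like gene TM4SF1 (-3.75 ± 0.10). Ribosome biogenesis genes had 45 of 49 members lower and 1 higher (1 and 46 adjusted over the list alone; camera adjusted p = 1.57e-17, adjusted p = 0.0357 with an estimated correlation). All 25 S-phase genes were lower (0 and 25 adjusted over the list alone; camera adjusted p = 2.7e-14, adjusted p = 0.0731 with an estimated correlation). G2/M-phase genes had 14 of 25 higher and 2 lower (14 and 2 adjusted over the list alone; camera adjusted p = 0.00465, adjusted p = 0.31 with an estimated correlation), with the cyclin-dependent kinase CDK1 at 0.82 ± 0.04. Androgen-induced genes had 18 of 33 lower and 8 higher (8 and 19 adjusted over the list alone; camera adjusted p = 1.36e-05, adjusted p = 0.144 with an estimated correlation). In all 4568 genes were higher and 4394 lower of 15132 tested. The DMSO libraries were taken at 24 h.

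At 24 h in LNCaP, with time-matched DMSO, KLK3, KLK2 and TMPRSS2 were lower in mean than at 12 h. KLK3 fell by 5.18 ± 0.04 on the log2 scale (from 2154 ± 61.5 to 59.5 ± 4.5 CPM; adjusted p = 2.15e-48), KLK2 by 5.45 ± 0.07 (from 374 to 8.53 CPM) and TMPRSS2 by 3.95 ± 0.05. TM4SF1 (-6.33 ± 0.13), FRMPD2 (-6.22 ± 0.21), C9orf152 (-6.21 ± 0.21) and the sialyltransferase gene ST6GALNAC1 (-5.53 ± 0.23) completed the largest falls above the expression floor. The bHLH factor gene HES6 (chromosome 2, 238238267 to 238240662) rose by 3.75 ± 0.05 (from 55.2 to 742 CPM), HERC5 by 3.32 ± 0.09, the protease gene TLL2 by 3.04 ± 0.16, protein S, PROS1, by 3.00 ± 0.10, SSPO by 2.98 ± 0.08 and MT1X by 2.94 ± 0.09. MYC was at -1.82 ± 0.05, FOXA1 at 0.50 ± 0.04, FKBP5 at -0.25 ± 0.05 and SPDEF at -2.84 ± 0.07. SMARCA2 (-0.07 ± 0.06), SMARCA4 (0.00 ± 0.04) and PBRM1 (0.05 ± 0.04) were not called, and ERG, at 0.904 CPM in DMSO, was not called either. In all 5154 genes were higher and 5211 lower, 68.5% of those tested, with 1092 and 1492 changed by at least 2-fold.

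None of the lists called in LNCaP at 24 h passed with an estimated correlation. That test had 3 residual degrees of freedom here against 5 in the longer VCaP experiment, so the lines cannot be compared by it. S-phase genes were lower in all 25 members (0 and 25 adjusted over the list alone; median -2.20; camera adjusted p = 1.91e-16, adjusted p = 0.0549 with an estimated correlation), with RRM2, a ribonucleotide reductase subunit, at -2.85 ± 0.06. G2/M-phase genes were lower in 24 of 25 members (1 and 24 adjusted over the list alone; median -2.01; camera adjusted p = 4.41e-16, adjusted p = 0.0549 with an estimated correlation), with MKI67 at -2.44 ± 0.05 (from 303 to 55.9 CPM) and the topoisomerase TOP2A at -2.28 ± 0.05. Of 49 ribosome biogenesis genes 46 were lower and 2 higher (2 and 46 adjusted over the list alone; camera adjusted p = 3.97e-14, adjusted p = 0.0518 with an estimated correlation). Hypoxia-induced genes had 15 of 18 lower and 2 higher, ADM and NDRG1 (2 and 15 adjusted over the list alone; camera adjusted p = 9.27e-08, adjusted p = 0.0549 with an estimated correlation), with lactate dehydrogenase, LDHA, at -1.56 ± 0.04. Integrated stress response genes had 17 of 22 lower and only ATF3 higher (1 and 17 adjusted over the list alone; camera adjusted p = 9.27e-08, adjusted p = 0.0549 with an estimated correlation). Chaperone genes had 17 of 18 lower and EDEM1 higher (1 and 17 adjusted over the list alone; camera adjusted p = 9.19e-09, adjusted p = 0.0735 with an estimated correlation). Lineage factors had 10 of 15 lower, including the epithelial ETS factor EHF (-1.63 ± 0.04), and 3 higher, FOXA1, TRPS1 and ONECUT2 (3 and 10 adjusted over the list alone; camera adjusted p = 0.00704, adjusted p = 0.138 with an estimated correlation). Androgen-induced genes had 21 of 33 lower and 8 higher, with MAF, NNMT and PLPP1 the highest (8 and 21 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.214 with an estimated correlation). Genes induced by p53 had 12 of 20 lower, among them GDF15 (-3.12 ± 0.05) and CDKN1A (-2.87 ± 0.07), and 4 higher, led by TP53I3 (4 and 12 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.214 with an estimated correlation). SWI/SNF subunits had 13 of 27 higher, led by ARID2 (1.00 ± 0.05) and ARID1A (0.88 ± 0.04), and 4 lower, with ACTL6A the lowest (13 and 4 adjusted over the list alone; camera adjusted p = 0.0278, adjusted p = 0.166 with an estimated correlation). Members of these lists outside the naming rule were named after their values were seen.

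Between 12 and 24 h in LNCaP the cell division genes fell. There was no 12 h vehicle, so length of treatment and time in culture cannot be told apart here either. All 25 G2/M-phase genes were lower at 24 h than at 12 h (0 and 25 adjusted over the list alone; median -2.18; camera adjusted p = 1.77e-44, adjusted p = 0.0309 with an estimated correlation). S-phase genes were lower in 24 of 25 (0 and 24 adjusted over the list alone; median -1.26; camera adjusted p = 3.63e-24, adjusted p = 0.0309 with an estimated correlation). The centromere chaperone HJURP (-2.75 ± 0.09) and the DNA glycosylase NEIL3 (-2.63 ± 0.13) were among the largest falls, with C9orf152 (-3.13 ± 0.29). IGFBP3, an insulin-like growth factor binding protein (1.81 ± 0.13), HES6 (1.67 ± 0.04) and SH3D21 (1.34 ± 0.08) rose most. KLK3 was lower at 24 h than at 12 h (-2.34 ± 0.04). In all 2553 genes were higher at 24 h and 2793 lower. Against DMSO 3874 genes were higher and 3841 lower at both times, and 193 were opposite, where independent lists would share 1556 and 1513. Simulated unchanged groups shared a mean of 0.6 calls, with a mean correlation of 0.511 between their log2 changes. Those calls cannot gauge the excess, part of which may come from the shared controls.

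**Figure D3:**
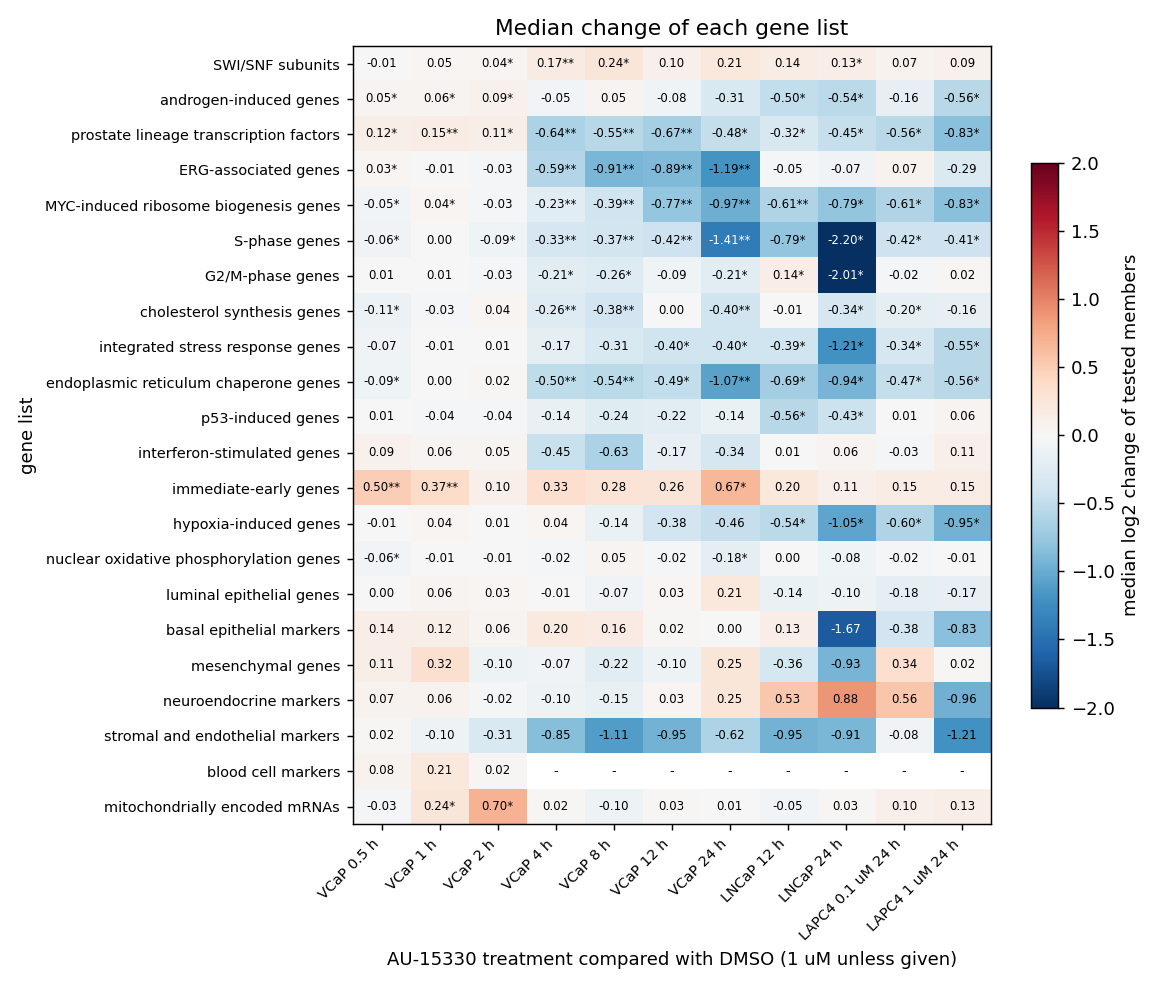
Median log2 change of the members of each gene list (1 list per line) in each comparison with DMSO (columns), coloured by value. A single asterisk marks a camera adjusted p under 0.05 with the preset correlation, a double asterisk also with the estimated one, and a dash fewer than 5 tested members; S-phase genes reach -2.20 in LNCaP and -1.41 in VCaP at 24 h.

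The LAPC4 experiment addresses a further line and the effect of dose. At 0.1 µM STC1, which encodes the secreted factor stanniocalcin, fell by 4.99 ± 0.12 on the log2 scale (from 33.6 to 1.05 CPM; adjusted p = 3.34e-181), the cytochrome P450 gene CYP4F8 by 3.81 ± 0.06 and the keratin KRT80 by 3.49 ± 0.08. SHISA2 (3.53 ± 0.08), the zinc finger gene ZNF521 (3.37 ± 0.08) and the potassium channel gene KCNJ2 (3.35 ± 0.11) rose most. MYC was at -1.04 ± 0.05 and KLK3 at -1.73 ± 0.05. TMPRSS2 was at -0.78 ± 0.04, FOXA1 at -0.18 ± 0.04 and FKBP5 at 0.74 ± 0.04. Of 49 ribosome biogenesis genes 46 were lower and 2 higher (2 and 46 adjusted over the list alone; camera adjusted p = 1.54e-20, adjusted p = 0.184 with an estimated correlation). Hypoxia-induced genes had 15 of 18 lower (2 and 15 adjusted over the list alone; camera adjusted p = 8.36e-09, adjusted p = 0.39 with an estimated correlation). In all 4854 genes were higher and 4778 lower of 16426 tested.

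At 1 µM, against the same DMSO libraries at 24 h, KLK3 and KLK2 were among the largest falls in LAPC4. KLK3 fell by 5.49 ± 0.07 on the log2 scale (from 148 ± 5.23 to 3.3 ± 0.182 CPM), KLK2 by 5.40 ± 0.08 (from 88.5 to 2.1 CPM; adjusted p = 2.31e-279), the secreted lectin gene ZG16B by 5.89 ± 0.12, CYP4F8 by 5.65 ± 0.07, KRT80 by 5.02 ± 0.09 and the stress-induced gene NUPR1 by 4.47 ± 0.08. The rises were led by the BH3-only gene BMF (3.92 ± 0.10), KCNJ2 (3.80 ± 0.11), ZNF521 (3.73 ± 0.08), the semaphorin SEMA3D (3.26 ± 0.05; from 16.8 to 161 CPM), the adhesion receptor ADGRB3 (3.13 ± 0.09) and SHISA2 (3.10 ± 0.09). MYC was at -1.55 ± 0.05, SPDEF at -3.40 ± 0.05 (from 127 to 12 CPM), TMPRSS2 at -1.50 ± 0.04 and FKBP5 at 0.43 ± 0.04, while FOXA1 at -0.07 ± 0.04 was not called (adjusted p = 0.089). SMARCA2 rose (0.48 ± 0.04), SMARCA4 fell (-0.26 ± 0.04) and PBRM1 rose (0.12 ± 0.04). Ribosome biogenesis genes had 47 of 49 lower and 2 higher (2 and 47 adjusted over the list alone; camera adjusted p = 1.73e-21, adjusted p = 0.173 with an estimated correlation). S-phase genes had 24 of 25 lower (1 and 24 adjusted over the list alone; camera adjusted p = 7.77e-08, adjusted p = 0.295 with an estimated correlation). Lineage factors had 10 of 15 lower and 1 higher (1 and 11 adjusted over the list alone; camera adjusted p = 4.28e-06, adjusted p = 0.295 with an estimated correlation). Androgen-induced genes had 21 of 33 lower and 11 higher, ADAM7, MAF and STEAP2 the highest, named after their values were seen (11 and 21 adjusted over the list alone; camera adjusted p = 0.000298, adjusted p = 0.634 with an estimated correlation). In all 5545 genes were higher and 5797 lower (69% of those tested), 828 and 1653 by at least 2-fold. The LAPC4 groups differed at very low counts. Of olfactory receptor genes 65.6 and 55.9% were detected in DMSO, 66.4 and 65.4% at 0.1 µM and 18.1 and 18.4% at 1 µM. In LNCaP the share was 15.7 to 18.9%, so it was the DMSO and 0.1 µM libraries that lay far from that line. Among genes at 1 CPM or more in at least 2 libraries, 5267 were higher and 5206 lower, 682 and 886 by at least 2-fold.

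The direct comparison of the doses addresses which genes differ between them. KLK3 (-3.76 ± 0.07), KLK2 (-3.75 ± 0.08), ZG16B (-3.24 ± 0.15), SPDEF (-2.75 ± 0.05; from 80.8 to 12 CPM) and NDRG1 (-1.57 ± 0.04; from 158 to 53.4 CPM) were lower at 1 µM than at 0.1 µM. MYC (-0.51 ± 0.05) and TMPRSS2 (-0.71 ± 0.04) were lower by less. The largest rises were in the follistatin-like gene FSTL5 (1.01 ± 0.10), PROS1 (0.90 ± 0.07) and CTTNBP2 (0.84 ± 0.08). Androgen-induced genes had 18 of 33 lower and 4 higher (4 and 19 adjusted over the list alone; camera adjusted p = 2.64e-17, adjusted p = 0.238 with an estimated correlation). Ribosome biogenesis genes had 40 of 49 lower (0 and 41 adjusted over the list alone; camera adjusted p = 8.38e-16, adjusted p = 0.238 with an estimated correlation). In all 2240 genes were higher and 2709 lower, 28 and 697 by at least 2-fold, against 8 and 150 among genes at 1 CPM or more in at least 2 libraries. Both doses against DMSO shared 4456 higher and 4381 lower genes with 73 opposite, where independent lists would share 1639 and 1686. For these doses simulated unchanged groups shared a mean of 0.35 calls, with a mean correlation of 0.512 between their log2 changes. Those calls cannot gauge the excess, part of which may come from the shared controls. The total of 4949 was 2649 without 0.1 µM replicate 1, 2684 without 0.1 µM replicate 2, 3122 without 1 µM replicate 1 and 2855 without 1 µM replicate 2.

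**Figure D4:**
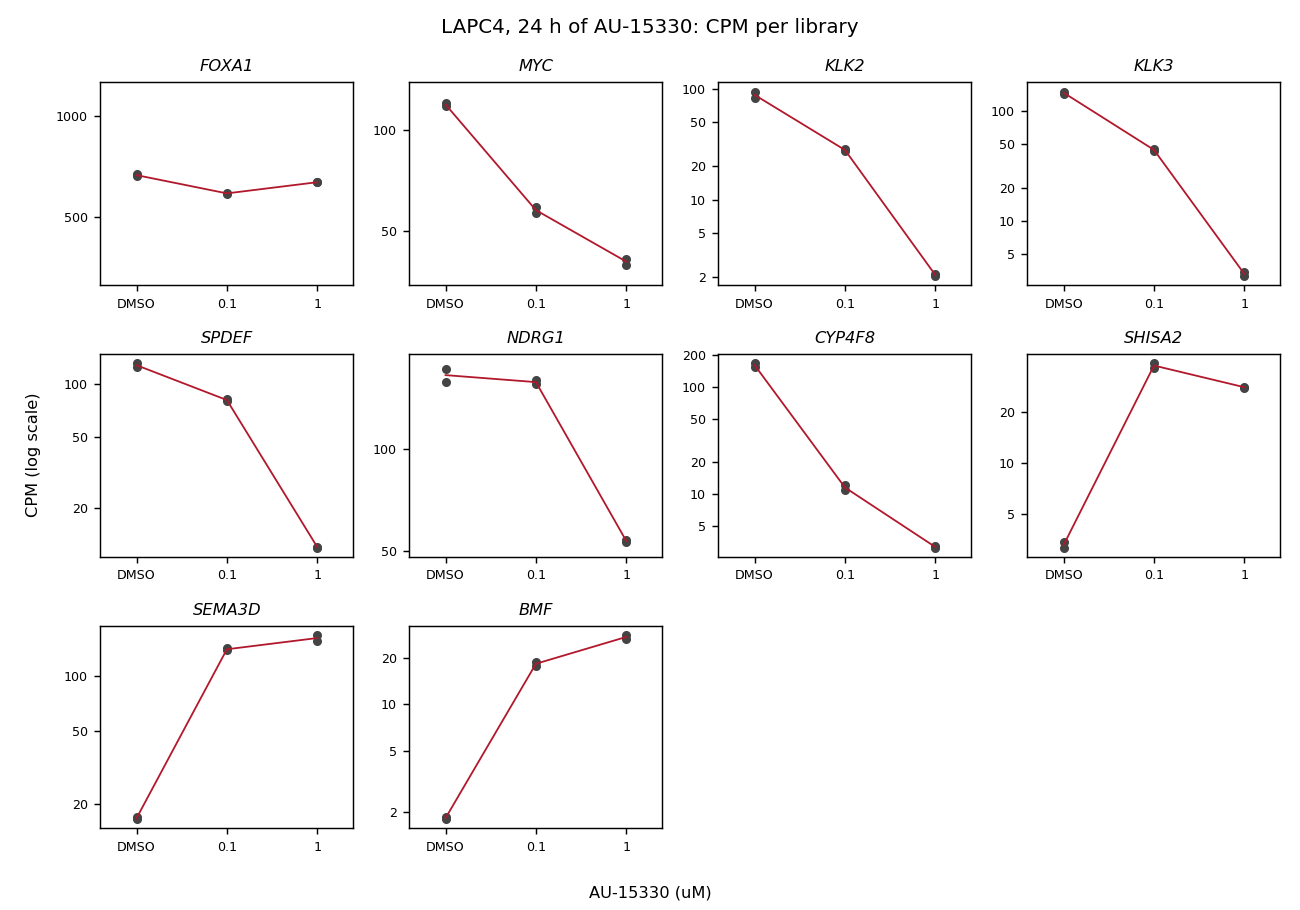
CPM on a log axis for 10 genes in LAPC4 after 24 h, by group (DMSO, AU-15330 0.1 µM and 1 µM), with a point per library and a red line through the group means. KLK3 goes from 148 CPM in DMSO to 44.6 at 0.1 µM and 3.3 at 1 µM, and NDRG1 from 166 to 53.4.

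Setting the 24 h, 1 µM changes of the lines side by side addresses which recur in separate lines, each with its own DMSO libraries. KLK2 fell in all 3, at -6.19, -5.45 and -5.40 in VCaP, LNCaP and LAPC4, as did KLK3 (-2.96, -5.18 and -5.49), SPDEF (-2.04, -2.84 and -3.40) and MYC (-1.40, -1.82 and -1.55). ZG16B (-7.52, -4.77 and -5.89), TSPAN1 (-4.71, -2.79 and -3.37) and the glucose transporter SLC2A1 (-2.01, -1.83 and -1.74) did too. Higher in all 3 were MAF (4.89, 1.88 and 1.74), the NFAT factor NFATC4 (2.86, 2.74 and 2.30), the inhibitor of differentiation ID2 (1.72, 1.88 and 2.45) and SMARCA1, an ATPase of another remodelling family (3.12, 1.58 and 3.36). TSPAN1, NFATC4, ID2 and SMARCA1 were chosen after their values were seen. Of 14409 genes tested in all 3 lines, 2446 were higher and 2468 lower in every line, where independent lists would share 637 and 568. Those numbers take every gene as equally likely to be called, so the excess alone does not measure a shared response. At a change of at least 2-fold in each line the shared genes were 202 and 249, where independent lists would share 4.17 and 5.85. Calls at low counts in LAPC4 are uncertain, since its DMSO libraries detected far more olfactory receptor genes than its 1 µM libraries. Pairwise, VCaP and LNCaP shared 3254 higher and 3309 lower genes with 946 opposite. VCaP and LAPC4 shared 3221 and 3205 with 1315 opposite, and LNCaP and LAPC4 3346 and 3315 with 1216 opposite.

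**Figure D5:**
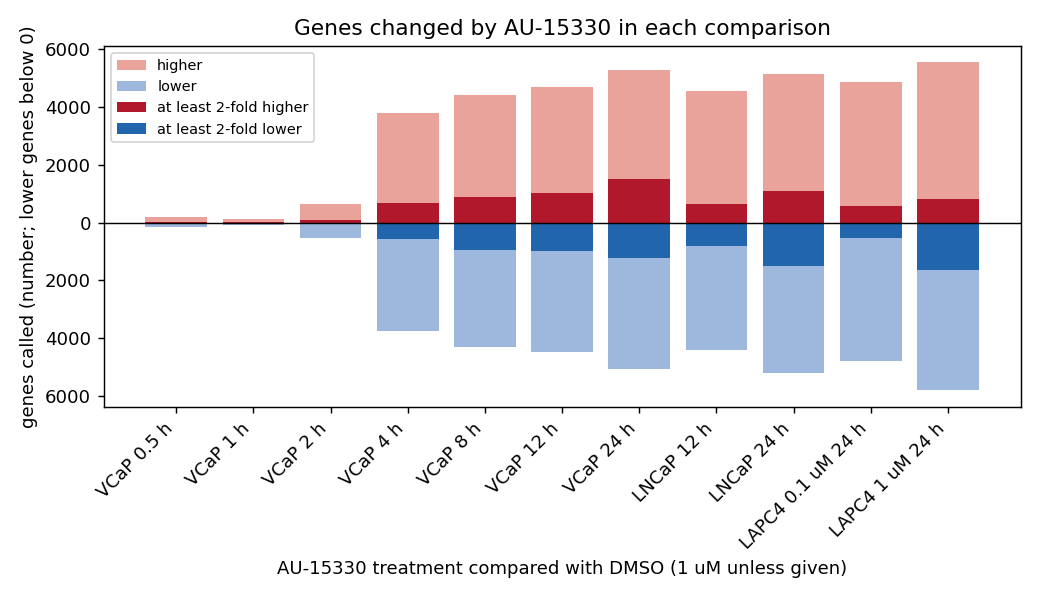
Genes past an adjusted p of 0.05 in the 11 comparisons with DMSO, as numbers of genes higher (bars upward) and lower (bars downward), with the dark part changed by at least 2-fold. Counts go from 215 at 1 h to 10346 at 24 h in VCaP, with 10365 in LNCaP and 11342 in LAPC4 at 24 h.

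Tests of the difference between lines address which effects depend on the cell line, a positive value meaning a higher effect in the line named first. TMPRSS2 fell less in VCaP (321 to 251 CPM) than in LNCaP (617 to 39.7 CPM), a difference of 3.61 ± 0.07 (adjusted p = 2.28e-47), and less than in LAPC4 by 1.14 ± 0.06. FOXA1 fell in VCaP and rose in LNCaP, with a difference of -1.33 ± 0.05, and the VCaP and LAPC4 effects differed by -0.77 ± 0.05. KLK3 differed by 2.21 ± 0.17 between VCaP and LNCaP and by 2.51 ± 0.18 between VCaP and LAPC4. NDRG1 rose in VCaP and fell in LAPC4, a difference of 3.58 ± 0.06. LBH, a transcription cofactor gene, rose in VCaP (0.543 to 12.9 CPM) and differed from LNCaP by 6.77 ± 0.57. The chemokine receptor ACKR3 (4.06 to 24.3 CPM in VCaP, 4.07 to 0.442 in LAPC4) differed by 5.79 ± 0.22, and HES6 in LNCaP differed from LAPC4 by 4.82 ± 0.08. The effect on G2/M-phase genes was lower in LNCaP than in LAPC4 in 24 of 25 members (0 and 24 adjusted over the list alone; camera adjusted p = 1.43e-31, adjusted p = 0.00891 with an estimated correlation). It was higher in VCaP than in LNCaP in 23 (23 and 1 adjusted over the list alone; camera adjusted p = 3.08e-27, adjusted p = 0.0169 with an estimated correlation). S-phase genes had a lower effect in VCaP than in LAPC4 in 24 of 25 members (0 and 24 adjusted over the list alone; camera adjusted p = 4.5e-19, adjusted p = 0.0397 with an estimated correlation). ERG-associated genes had a lower effect in VCaP than in LNCaP in 13 of 16 (1 and 13 adjusted over the list alone; camera adjusted p = 4.8e-08, adjusted p = 0.0555 with an estimated correlation). Of 16342 genes tested, 7085 effects differed between VCaP and LNCaP, 7580 between VCaP and LAPC4 and 7417 between LNCaP and LAPC4. The numbers with LAPC4 may include genes at low counts, where calls in that line are uncertain. Cell line and experiment are the same split here, so a difference between lines cannot be told apart from a difference between experiments.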

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

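The tests of depth and graded dose for the LAPC4 background, of a lasting immediate-early response and of the mitochondrially encoded mRNAs were chosen after the results were seen. The differences between cell lines and times were tests chosen beforehand. A difference between lines or times was what drew attention to each value here. Positive values mean a higher effect in the line named first or a higher level at the later time. The earlier treated libraries had no vehicle of their own time, so treatment and time in culture cannot be told apart there.

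Effects of 24 h at 1 µM differed between VCaP and LNCaP for 7085 genes. TMPRSS2 differed by 3.61, KLK3 by 2.21, FKBP5 by 0.85, MYC by 0.41, SMARCA2 by 0.47, SMARCA4 by -0.23, FOXA1 by -1.33 and LBH, at 0.888 CPM in LNCaP DMSO, by 6.77. The median difference over G2/M-phase genes was 1.74 (adjusted p = 0.0169 with an estimated correlation).

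Between VCaP and LAPC4 7580 genes differed. KLK3 differed by 2.51, TMPRSS2 by 1.14, FKBP5 by 0.16, FOXA1 by -0.77, ACKR3 by 5.79 and LBH by 5.68, and S-phase genes had a median of -1.04 (adjusted p = 0.0397 with an estimated correlation). Between LNCaP and LAPC4 7417 genes differed. HES6 differed by 4.82, FOXA1 by 0.56, KLK3 by 0.30, SMARCA4 by 0.25, SMARCA2 by -0.57, MYC by -0.28, FKBP5 by -0.69 and TMPRSS2 by -2.47. Medians were -1.96 for G2/M-phase genes (adjusted p = 0.00891 with an estimated correlation), -1.72 for S-phase genes (adjusted p = 0.00891 with an estimated correlation) and -0.49 for integrated stress response genes (adjusted p = 0.0382 with an estimated correlation). Cell line and experiment are the same split, and no explanation of these differences was tested.

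Within VCaP 8958 genes differed between 24 and 4 h. KLLN (4.23), SYT2 (3.89), NCMAP (3.10), TMPRSS2 (0.91) and ERG (0.15) were higher at 24 h. SFTPA2 (-5.08), KLK2 (-4.55), SLC17A4 (-4.51), KLK3 (-1.75), FKBP5 (-1.68), SMARCA4 (-0.25), MYC (-0.17) and PBRM1 (-0.14) were lower. The median was -1.24 over S-phase genes (adjusted p = 0.0107 with an estimated correlation) and -0.70 over ribosome biogenesis genes (adjusted p = 0.0107 with an estimated correlation). Within LNCaP 5346 genes differed between 24 and 12 h. IGFBP3 (1.81), HES6 (1.67), SH3D21 (1.34) and FOXA1 (0.32) were higher at 24 h. C9orf152 (-3.13), HJURP (-2.75), NEIL3 (-2.63), KLK3 (-2.34), TMPRSS2 (-0.66), MYC (-0.49), FKBP5 (-0.37) and SMARCA2 (-0.21) were lower. The median was -2.18 over G2/M-phase genes, -1.26 over S-phase genes, -0.67 over integrated stress response genes, -0.55 over hypoxia-induced genes and -0.39 over cholesterol synthesis genes (each adjusted p = 0.0309 with an estimated correlation).

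More olfactory receptor genes, which are weakly expressed in most tissues, were detected in the LAPC4 libraries of DMSO and 0.1 µM than in those of 1 µM: 65.6 and 55.9% of them in DMSO, 66.4 and 65.4% at 0.1 µM and 18.1 and 18.4% at 1 µM. The range was 15.7 to 18.9% in LNCaP, 10.8 to 13.4% in the longer VCaP experiment and 30.3 to 32.3% in the short one. A lower depth at 1 µM is argued against, since the shallower 1 µM library held 1.7 M counts more than the deeper DMSO library. An effect on such genes that grows with dose was not decided. The mean share detected was 5.15 points higher at 0.1 µM than in DMSO, less than the 9.7 points between the DMSO libraries. Counts summed over 845 genes with no count in LNCaP or the longer VCaP experiment fell, from 16809 in DMSO to 7205 at 0.1 µM and 2685 at 1 µM, but CALML5, named after its values were seen, held most of the DMSO sum. Without it the libraries held 2874 and 1932 in DMSO, 2184 and 2307 at 0.1 µM and 624 and 789 at 1 µM. A background that follows gene length, such as genomic DNA, would give more counts to longer genes, and over the same genes, which are not independent replicates, exonic length and counts had a Spearman rho of 0.388 in DMSO, as such a background would give. The same correlation was 0.4168 at 0.1 µM and 0.2415 at 1 µM, where most of these counts were gone, so length alone does not single out a background. Such a background, a graded effect and an effect at 1 µM alone all stay open, and each leaves calls at low counts in LAPC4 uncertain.

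Immediate-early genes were higher at 0.5 h, where the only vehicle libraries were taken at 2 h. Handling at the time of dosing could raise them, and then the 0.5 h calls should not recur in the other VCaP experiment. Of 304 such genes tested at 4 h, 21.4% were called in the same direction and 55.9% in the opposite one, a difference of -34.5 points. By its letter this met the bound set beforehand for handling, an excess of same-direction calls of at most 10 points. That bound did not foresee an excess of opposite calls, so it was later narrowed to 10 points either way. The result was then read as neither favouring nor excluding handling. The 4 h calls also rest on DMSO taken at 24 h. A degrader response that lasts to 2 h was not decided either, with a list median of 0.1025 at 2 h and members that went both ways. The median was 0.0555 with library totals only, below the bound of 0.1 set against such a response, so this test depends on the scaling. Without a 0.5 h vehicle, handling and a degrader response cannot be told apart.

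Mitochondrially encoded mRNAs were higher at 2 h in VCaP, with a median of 0.70. A degrader effect that lasts to 4 h should raise the list median at 4 h in the other experiment, which was 0.0234. The DMSO libraries there were taken at 24 h, so that value mixes treatment with time in culture and cannot exclude such an effect. A shorter effect stays open too. A uniformly higher yield of mitochondrial RNA in the 2 h libraries should move all 13 mRNAs alike, and 3 differed from the median by more than 0.3 on the log2 scale and 2 SE, MT-CO1 by -0.41, MT-ND3 by 0.31 and MT-ND6 by -1.14. A further 4, MT-ATP6, MT-ATP8, MT-CO2 and MT-CO3, differed by more than 2 SE but by less than 0.3. The number past both limits lay between the bounds set for the test, and MT-ND6 is transcribed from the other strand, with the strand counted not given in the sources used here. A different yield and an effect of the degrader, short or lasting, therefore cannot be told apart from these libraries.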

How the results depend on the processing

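The tests with mitochondrially encoded genes left out were chosen after seeing the data, and the other tests here beforehand. Totals of changed genes, overlaps and interactions gave 195 values under the alternatives within 1.5 times the reported count and 22 outside it. Parts of the totals and interactions, higher or lower and by at least 2-fold, gave 748 within and 60 outside. Named genes and lists gave 16047 values with the same direction and side of the threshold, 145 newly past it, 467 no longer past it and 1 reversed. The comparisons from 4 h on with DMSO kept their totals within 1.5 times under every alternative. Their near-even split by direction depended on the scaling. With library totals only, higher calls went from 51 to 58.3% in LNCaP at 12 h and from 49.7 to 54.6% at 24 h. In LAPC4 they went from 50.4 to 58.6% at 0.1 µM and from 48.9 to 55.4% at 1 µM. In VCaP at 24 h they went from 51.2 to 53.3%.

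Counts in the short VCaP experiment lay outside that range under several alternatives. At 0.5 h the 323 calls were 206 with DESeq2, 564 with no filter on low counts and 901 when only its 4 libraries were fitted. The cause was not tested. The fit of all groups took 1 shared spread, but replicates did not differ equally in each group. The mean chi-square per gene between replicates was 2.875 in DMSO, 2.855 at 0.5 h, 5.478 at 1 h and 6.166 at 2 h. At 1 h the 215 calls were 411 with no filter, and the cause was not tested. Leaving out 1 library at a time gave 99 to 138 calls at 0.5 h, 70 to 225 at 1 h and 637 to 998 at 2 h (from 1180). With mitochondrially encoded genes left out the totals were 325, 200 and 1157 in the same order, all within 1.5 times the reported ones.

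Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups, and fewer samples alone lower the counts. The comparison of the LAPC4 doses gave 2649 to 3122 (from 4949) calls. Against DMSO the range was 6264 to 6490 (from 7538) in VCaP at 4 h, 9301 to 9542 (from 10346) at 24 h, 9305 to 9800 (from 10365) in LNCaP at 24 h and 10096 to 11279 (from 11342) in LAPC4 at 1 µM. A single list result reversed. Ribosome biogenesis genes at 1 h had a camera adjusted p of 0.04176 and, in the opposite direction, 0.8355 without 1 h replicate 2, over a range of 9.694e-05 to 0.8355 when each library was left out. The cause was not tested. Among other named genes and lists 6880 values stayed the same, 300 were no longer past the threshold and 35 newly past it.

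Requiring a change of at least 2-fold lowered every overlap, because fewer genes then qualify. It left 451 genes shared by the 3 lines, 936 by VCaP and LNCaP, 801 by VCaP and LAPC4, 840 by LNCaP and LAPC4 and 53 by VCaP at 2 and 4 h. With library totals as the only scaling 1148 values of named genes, called or not, stayed on the same side of the threshold. With DESeq2 size factors 1148 did, with the DESeq2 test 1123 and with no filter 1144. Those no longer past the threshold were 4, 6, 29 and 10. The list tests were not repeated under these settings. With an estimated correlation 99 of the list calls were lost and 261 list results stayed the same. That test also rests on few residual degrees of freedom, so the losses do not measure correlation alone. The fry test, which does not compare a list with other genes, gave 94 further calls and 7 fewer.

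With a replicate block the counts were 270 in VCaP at 0.5 h, 174 at 1 h, 1085 at 2 h and 10325 at 24 h, 10311 in LNCaP at 24 h and 11209 in LAPC4 at 1 µM, each within 1.5 times the reported one. The labels do not say whether libraries with the same replicate number share more than that number. Correlations of their deviations from the group means had a median of -0.076 in the short VCaP experiment (range -0.234 to 0.161). The medians were -0.004 in the longer one, -0.023 in LNCaP and 0.019 in LAPC4. Depth limits genes near 1 CPM, which stood for 23.6 reads in the shallowest LNCaP library. In LAPC4 at 1 µM the genes lower by at least 2-fold numbered 886 instead of 1653 when at least 1 CPM in at least 2 libraries was required, because fewer low genes were tested.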

Other observations

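The gene families here were all chosen after the results were seen, and no enrichment test was run on them. Their counts come from the comparisons of 24 h at 1 µM with DMSO unless another time is given. Over all genes tested, 5292 were higher and 5054 lower of 15747 in VCaP. In LNCaP 5154 were higher and 5211 lower of 15132, and in LAPC4 5545 and 5797 of 16426. Family counts near these shares do not set a family apart. Zinc finger genes with symbols starting ZNF had 220 higher and 87 lower of 483 in VCaP (median 0.20), 238 higher and 89 lower of 478 in LNCaP (0.24) and 281 higher and 91 lower of 492 in LAPC4 (0.23). Mitochondrial ribosomal protein genes had 4 higher and 47 lower of 78 in VCaP (median -0.27), 6 higher and 49 lower of 78 in LNCaP (-0.25) and 12 higher and 44 lower of 78 in LAPC4 (-0.16). Translation initiation factors had 4 higher and 35 lower of 55 in VCaP (median -0.26), 4 higher and 39 lower of 55 in LNCaP (-0.31) and 8 higher and 37 lower of 55 in LAPC4 (-0.22). Subunits of the cytosolic chaperonin, which folds actin and tubulin, had 0 higher and 8 lower of 9 in VCaP (median -0.50), 1 higher and 8 lower of 9 in LNCaP (-0.54) and 0 higher and 8 lower of 9 in LAPC4 (-0.38).

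Members of the HOXC cluster, which encode homeobox factors, had 6 higher and 1 lower of 8 in VCaP (median 1.58), 4 higher and 0 lower of 8 in LNCaP (0.83) and 6 higher and 0 lower of 7 in LAPC4 (0.75). Protocadherin genes had 34 higher and 4 lower of 59 in VCaP (median 0.43). They had 30 higher and 5 lower of 54 in LNCaP (0.39) and 14 higher and 20 lower of 64 in LAPC4 (-0.06). Earlier VCaP counts were 6 higher and 4 lower at 4 h, 10 and 18 at 8 h, and 30 and 4 at 12 h. In LNCaP at 12 h 4 protocadherin genes were higher and 9 lower. Their LAPC4 counts were 20 higher and 19 lower with library totals only, and 14 higher and 12 lower at 0.1 µM (median 0.10), and calls at low counts in that line are uncertain. Histone genes, most of which lack a poly(A) tail and share sequence with paralogs, had 24 higher and 9 lower of 57 in VCaP (median 0.14), 37 higher and 2 lower of 53 in LNCaP (1.07) and 6 higher and 41 lower of 60 in LAPC4 (-0.70), and 2 higher and 18 lower of 57 in VCaP at 4 h (median -0.70).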
